A study of Mus musculus with 27 samples.

How the data were processed

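The series holds 27 Affymetrix arrays of RNA from laser-captured mouse islets, 1 per sample. Per the labels, total RNA was linearly amplified in 2 rounds, biotin was the label, and the deposited values come from RMA, per the submitters' processing notes; its version and its settings are not given in the sources used here. RMA as a method includes background correction, quantile normalization and a summary per probe set. The deposited values are on a log2 scale, as their range and the even medians of the arrays show, and they were used without further scaling. Scanner images and probe-level intensities were not used here.

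The deposited table has 12488 probe sets. The 66 Affymetrix control probe sets were left out, and 12422 were tested. By the platform annotation, 10833 of these have 1 gene symbol, 396 have several and 1193 have none. Probe sets with 1 symbol stand for 8251 genes, of which 2073 have more than 1 probe set. A gene was represented by its probe set with the highest mean over all arrays. Of the Entrez identifiers, 10817 were found in the GRCm38.p6 gene table. By the maker's naming, probe sets whose names end in _s_at, _f_at, _r_at or _i_at hold probes shared between transcripts or chosen under relaxed rules; among the named genes these are Socs3, Ero1b, Cox6b2, Gadd45b, Kifc1, Kif20a, Tie1, Abcc8, Txnip, Reg3b and H2-K1, and both Ins2 probe sets.

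Groups were taken from the labels, 3 arrays in each of 9 groups. The 10 comparisons set each time after injection and the 21 day course against untreated islets, 21 days against 24 h, each time after withdrawal against 21 days, and 6 days off against untreated. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values of all 27 arrays, 9 group means and 18 residual degrees of freedom, two-sided. Benjamini-Hochberg adjustment ran over the 12422 probe sets of a comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. For 3 arrays against 3, a permutation of the arrays of 1 comparison has 10 splits and cannot give p under 0.1, so no permutation p is given for genes.

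The comparisons, the tests, the rule for naming genes, 31 gene lists and most of the other settings tried were fixed before the data were examined. The lists were written from general knowledge of Myc targets, cell growth and division, stress responses, beta cells and other cells an islet section can hold; 1057 of 1500 list symbols matched the array. Each list was tested in each comparison with limma's camera at a preset correlation of 0.01, and the adjustment ran over all 310 tests. Of these, 109 were called, and 2 of the 109 held with a correlation estimated from the data, ribosome biogenesis at 2 h and at 4 h; fry, which tests whether a list moves on balance and compares it with no other genes, called 26 of the 310 tests. Counts adjusted over the list alone apply the adjustment within the list.

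Genes were named by rule. In each comparison these are the 10 largest rises and the 10 largest falls among genes that were called and whose 3 arrays of 1 group all lay above those of the other, and the 3 called members of each list with the largest change. A short panel, with Myc, Esr1, Ins2, Iapp, Pdx1, Slc2a2, Pcna, Mki67 and Il1b among its genes, could be named whether called or not. Not all genes open to naming are named. Other settings were followed for a selection of them with 194 called results, over which the counts of named genes that kept their call are taken, and not all of these are printed.

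The method was tested on simulated data made from the deposited values, in 5 tables per comparison with 200 changed probe sets each. For 4 h against untreated it recovered 41.8%, 84.8% and 98.5% of log2 changes of 0.5, 1 and 2, and 5.07% of calls were false. For 4 days off against 21 days it recovered 40.0%, 81.8% and 97.0%, and 4.21% of calls were false. The simulated noise was normal and independent between probe sets, so these shares do not cover variation that the probe sets of an array have in common. Simulations that kept the shifts called at 8 h and used the deviations of whole arrays called up to 415 genes there (mean 115.5), against 158 in the data.

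The other settings tried were median centring, quantile normalization, leaving out the 40% of probe sets with the lowest mean, a trend and robust variance, array weights, a fit of the 6 arrays compared, a block for the replicate number, the mean of a gene's probe sets, every probe set, a 2-fold minimum, and leaving out each array in turn. Chosen after seeing the data were a fit without 4 arrays whose leukocyte marker mean lay over 0.5 above that of all arrays, a fit with the mean acinar and leukocyte marker levels as covariates, a fit with Eif2s3y as a covariate, and a fit with the 3′ minus 5′ log2 signal of the Gapdh control as a covariate. The 4 arrays were replicate 1 at 2 h, replicate 3 at 8 h, replicate 2 at 2 days off and replicate 1 at 6 days off. Overlap counts were set against 200 simulated tables per pair that kept the shifts of called probe sets, shared the control arrays, and moved the shifts of the second group, or of all 12 later arrays for 8 h and 21 days, to other probe sets of like level. Genes that went back were set against 50 tables without change after withdrawal and 200 with those changes moved. A first form for 8 h and 21 days kept all group means, so that their noise came on top of the added noise; its 50 tables called up to 2520 genes at 8 h, and up to 567 in the same direction at both times, and it was put aside.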

Results

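RNA levels were measured in 27 arrays of laser-captured mouse pancreatic islets, in 9 groups of 3 arrays. The mice carried MycER, a Myc protein that is active while 4-hydroxytamoxifen is bound, and the survival protein BclXL, both driven by an insulin promoter. The groups were untreated mice, mice killed 2, 4, 8 or 24 h after an injection, mice dosed daily for 21 days, and mice left without drug for 2, 4 or 6 days after such a course. The median log2 level of an array lay between 6.91 and 7.01, and arrays of a group correlated across probe sets with r between 0.957 and 0.992; probe sets are not independent replicates. The 3′ signal of the Gapdh control exceeded its 5′ signal, a sign of RNA quality or amplification, by 4.83 ± 0.08 on the log2 scale at 21 days, 3.78 ± 0.11 at 24 h and 4.75 ± 1.02 in untreated islets. At 2, 4 and 6 days off drug the excess was 3.54 ± 0.65, 3.83 ± 0.32 and 3.92 ± 0.47, below that of each 21 day array. The actin control set 21 days against 24 h and the days off in the opposite order, with overlapping arrays. Its 3′ excess was 2.39 ± 0.35 at 21 days, 2.70 ± 0.24 at 24 h and 2.21 ± 0.14 in untreated islets. At 2, 4 and 6 days off it was 2.68 ± 0.31, 2.61 ± 0.31 and 2.85 ± 0.23. The 2 controls thus give no common ranking of RNA quality. Arrays give no read depth, and the 3 arrays per group limit the precision. The labels number the replicates without saying that each came from a separate mouse, so the p-values measure only the spread between these samples. Errors of log2 changes are standard errors (SE) from limma over all arrays, those of levels are standard deviations (SD), and n is 3 arrays per group throughout.

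Genes followed through the groups are placed here with their probe sets and GRCm38.p6 positions. They were Pdx1 (98821_at, chromosome 5, 147270097 to 147275848), Mki67 (99457_at, chromosome 7, 135689784 to 135716450) and Mx1 (98417_at, chromosome 16, 97447035 to 97462906). The others were Papss2 (96713_at, chromosome 19, 32595669 to 32667187), Dlk1 (101975_at, chromosome 12, 109452485 to 109463336) and Xbp1 (94821_at, chromosome 11, 5520641 to 5525993). Of the Ins2 probe sets, 100150_f_at stood near the top of the scale at 13.82 ± 0.07 in untreated islets, and 161849_r_at read 11.94 ± 0.06. The mouse Myc probe set (104712_at) read 3.76 ± 0.28 there and passed the test in none of the comparisons; at 2 h it was 1.11 ± 0.49 higher, adjusted p = 0.379. Control probe sets for bacterial transcripts read as low as 3.57 (TrpnX-3), 3.94 (DapX-3), 4.65 (LysX-M) and 5.05 (TrpnX-5) on average in the 12 arrays of long treatment and withdrawal, and 3.58, 3.79, 4.67 and 5.03 in the 15 others. Levels in this range were not shown to stand above background. They were read by Slc16a1 and Cks2 in untreated islets, by Gad1 at 4 h and 8 h, by Rnase1 at 21 days, and by Mx1 at 21 days and later, so the sizes of these changes are lower bounds if the low level is background. PheX-3 and ThrX-3, further bacterial controls, read 7.06 and 5.74 in the 12 arrays and 7.20 and 5.63 in the 15 others. Background may thus reach the untreated levels of Prim1 (5.14), Reg3a (5.41), Dtl (5.74), Reg3g (5.91), Mki67 (6.04), Cdc7 (6.11) and Top2a (6.11). The same holds for Pdx1 at 4 h (6.23), 8 h (5.92) and 21 days (6.05), and for Mx1 at 4 h (5.82) and 8 h (5.28). It holds for Papss2 at 8 h (5.99), at 21 days and at 6 days off, and for Mrps22 (5.66) and Sdha (6.00) at 21 days. Further named genes in this range are not all listed.

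**Figure D1:**
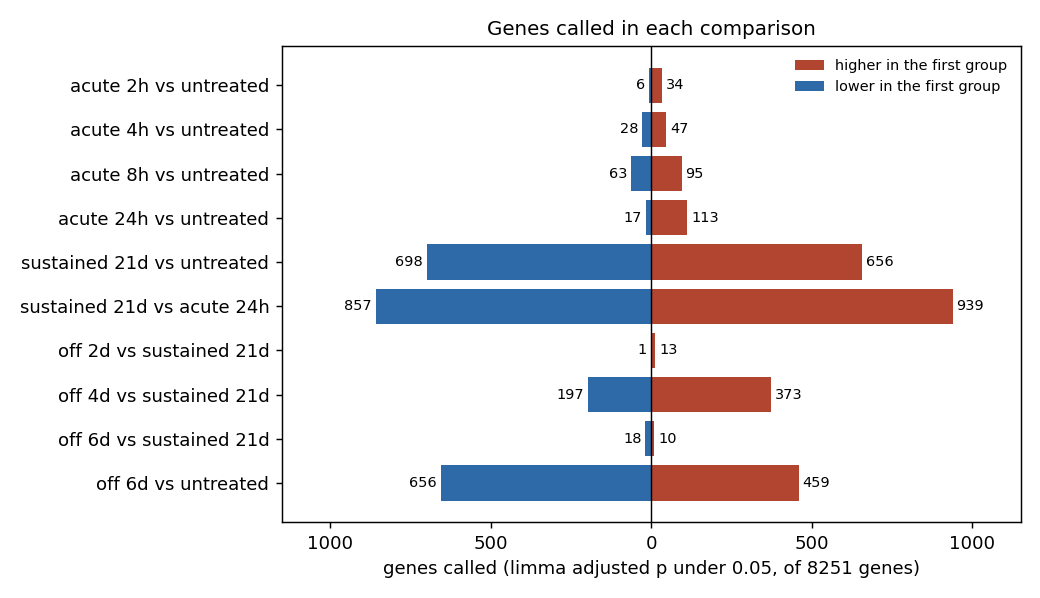
Number of genes called higher (right) and lower (left) in the first-named group of each comparison, of 8251 genes, at a limma adjusted p under 0.05 with n = 3 arrays per group. The bars run from 1 gene lower at 2 days off drug to 939 genes higher at 21 days against 24 h.

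The question at 2 h was which genes change first after the injection. The labels name no group injected without the drug and none without MycER. Effects of the injection, of the drug itself and of active MycER thus cannot be told apart at any time. Some genes of ribosome assembly rose. Utp4 was 1.07 ± 0.22 higher on the log2 scale (2.10-fold, 8.98 ± 0.05 against 7.91 ± 0.16), and Imp3 and Bop1 rose 1.82-fold and 1.81-fold; all 3 act in making ribosomal subunits. Bzw2 rose 2.47-fold (1.30 ± 0.16, adjusted p = 0.000501) and Eif4ebp1, a repressor of translation initiation, 2.23-fold. The largest rises were in Cebpd, a transcription factor of the acute phase (2.17 ± 0.45, adjusted p = 0.0301), and Socs3, a feedback inhibitor of cytokine signalling (2.02 ± 0.34). Fkbp5, a glucocorticoid-responsive chaperone, rose 2.20-fold, Slc16a1, a lactate transporter, by 0.98 ± 0.20 from a low 3.99 ± 0.16, and Mxi1, which competes with Myc for its partner Max, by 1.24 ± 0.24. Mdm2, the ubiquitin ligase of p53, fell by 0.56 ± 0.11. Other probe sets read -0.14 for Bop1 (adjusted p = 0.784) and 0.73 for Socs3 (adjusted p = 0.0422).

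Of the 69 measured genes of ribosome biogenesis, 6 rose, 0 fell and 63 were not called over all genes; adjusted over the list alone, 24 rose. The list rose against all other genes (median 0.39, camera adjusted p = 1.2e-25; adjusted p = 0.0463 with an estimated correlation). The 36 classical Myc induced genes had a median of 0.18 (adjusted p = 5.07e-06; adjusted p = 0.115 with an estimated correlation), with 1 called and 4 adjusted over the list alone. Markers of other cells were also higher: 23 of 24 acinar markers (median 1.46, adjusted p = 4e-09; adjusted p = 0.511 with an estimated correlation) and 45 of 52 leukocyte markers (median 0.52, adjusted p = 3.49e-10; adjusted p = 0.511 with an estimated correlation). No member of these marker lists was called by limma, with 7 acinar and 11 leukocyte markers higher at an unadjusted p under 0.05. Immediate early genes (median 0.42, 0 of 29 called, 7 adjusted over the list alone, adjusted p = 1.21e-07; adjusted p = 0.321 with an estimated correlation) were higher in the same arrays. Beta cell function genes were lower in 34 of 37 and did not pass as a list (median -0.12, adjusted p = 0.125; adjusted p = 0.883 with an estimated correlation), with 0 called, 0 adjusted over the list alone and 2 lower at an unadjusted p under 0.05. That list passed without untreated replicate 1 (adjusted p = 0.00341) or without 4 leukocyte-rich arrays (adjusted p = 0.0253). Pdx1 was -0.57 ± 0.20 and did not pass (adjusted p = 0.245).

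At 2 h limma called 40 genes, 34 higher and 6 lower. The count was 19 without untreated replicate 1 or 2, 20, 14 and 78 without replicate 1, 2 or 3 at 2 h, 90 with acinar and leukocyte covariates, and 0 in a fit of the 6 arrays alone (860 genes at an unadjusted p under 0.05). It was 103 with array weights, 20 without the 4 arrays richest in leukocyte markers and 17 with a 2-fold minimum. Of 16 named genes that were called, Bzw2, Imp3, Bop1, Eif4ebp1 and Fkbp5 kept the call without any 1 of the 6 arrays. Without the 4 leukocyte-rich arrays 8 of the 16 kept it, and with acinar and leukocyte covariates 12.

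At 4 h the ribosome biogenesis list was higher, and 3 of 37 beta cell function genes were called lower. Nhp2, a small nucleolar RNA-binding protein, rose 2.61-fold (1.39 ± 0.24) and Utp4 2.04-fold. Ccnd1, the G1 cyclin D1, rose by 1.25 ± 0.24 (10.34 ± 0.48 against 9.09 ± 0.15), Pdk1, a kinase that holds back pyruvate oxidation, 2.80-fold, and the nucleotide synthesis enzymes Adsl and Ctps 1.95-fold and 1.69-fold; the other Ccnd1 probe set read 0.093, adjusted p = 1. Gad1, the enzyme that makes GABA, fell by 2.39 ± 0.49, Mx1, an interferon-induced GTPase, by 2.25 ± 0.41, and Papss2, which makes the sulfate donor of the cell, by 1.49 ± 0.32. Pdx1, the transcription factor of beta cell identity, fell by 0.83 ± 0.20 (6.23 ± 0.12 against 7.06 ± 0.10, adjusted p = 0.0498). Of 37 beta cell function genes, 3 fell and 34 were not called, with 4 lower adjusted over the list alone (median -0.25, adjusted p = 1.14e-05; adjusted p = 0.497 with an estimated correlation). Of 69 ribosome biogenesis genes, 7 rose and 62 were not called, with 30 higher adjusted over the list alone (median 0.41, adjusted p = 8.82e-33; adjusted p = 0.0253 with an estimated correlation). The classical Myc induced genes had a median of 0.25, with 0 of 36 called and 5 higher adjusted over the list alone (adjusted p = 1.57e-07; adjusted p = 0.0654 with an estimated correlation). Acinar markers were higher in 23 of 24, with 0 called and 3 higher at an unadjusted p under 0.05 (median 1.23, adjusted p = 3.45e-07; adjusted p = 0.618 with an estimated correlation).

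At 4 h 75 genes were called, 47 higher and 28 lower. The count was 40 without untreated replicate 2, 16 without replicate 3 at 4 h, 14 in the 6 arrays alone and 23 with a 2-fold minimum. The calls of Adsl and Pdx1 ended in each of the 6 fits that left out 1 array, that of Pdx1 also with the Gapdh covariate, while those of Slc6a15, Cdca7, Pdk1, Bzw2 and Phb2 stayed. Between 2 h and 4 h, 21 genes were higher and 3 lower at both times, against 0.194 and 0.0204 for independent calls. Both comparisons used the same untreated arrays, and simulated tables that kept the called changes but moved those at 4 h to other genes gave 0 to 11 shared genes.

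At 8 h some genes of DNA replication rose. Cdc7, a kinase that starts replication, rose 3.02-fold (1.59 ± 0.34), Prim1, the primase subunit, 2.20-fold, Dtl, a ubiquitin ligase adaptor acting on replicating chromatin, 3.46-fold, and Ccnd1 2.49-fold (1.32 ± 0.24). Psat1, an enzyme of serine synthesis, rose 3.90-fold (1.96 ± 0.28, adjusted p = 0.000642). Mx1 fell by 2.80 ± 0.41, Papss2 by 2.63 ± 0.32, Gad1 by 2.60 ± 0.49, Th, which makes the precursor of dopamine, by 1.22 ± 0.29, and Pdx1 by 1.13 ± 0.20 (adjusted p = 0.00457). Slc2a2, the glucose transporter of beta cells, was -1.21 ± 0.42 and did not pass (adjusted p = 0.157), nor did Pcna, the replication clamp (1.37 ± 0.37, adjusted p = 0.0624). A second probe set of Ccnd1 read -0.037, adjusted p = 0.881.

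Of 57 DNA replication and G1/S genes, 9 rose, 0 fell and 48 were not called at 8 h; adjusted over the list alone 24 rose and 1 fell (median 0.44, adjusted p = 3.44e-15; adjusted p = 0.345 with an estimated correlation). Of 69 ribosome biogenesis genes, 6 rose and 63 were not called, 30 rose adjusted over the list alone (median 0.42, adjusted p = 1.36e-22; adjusted p = 0.0578 with an estimated correlation). Of 37 beta cell function genes, 6 fell and 31 were not called, 9 fell adjusted over the list alone (median -0.43, adjusted p = 7.84e-09; adjusted p = 0.321 with an estimated correlation). Mitosis and G2/M genes had a median of 0.21, with 2 of 56 called, Mad2l1 and Ran, and 3 adjusted over the list alone (adjusted p = 0.000114; adjusted p = 0.795 with an estimated correlation, 0.424 with acinar and leukocyte covariates). Acinar markers had a median of 1.11 with 0 of 24 called and 2 higher adjusted over the list alone (adjusted p = 2.12e-05; adjusted p = 0.721 with an estimated correlation) and leukocyte markers of 0.27 with 0 of 52 called and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.0106; adjusted p = 0.883 with an estimated correlation). Neither marker list held its call without replicate 3 at 8 h (adjusted p = 0.118 and 0.985).

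At 8 h 158 genes were called, 95 higher and 63 lower. The count was 51 without untreated replicate 2, 97 without replicate 1 and 102 without replicate 3 at 8 h, 4 in the 6 arrays alone and 40 with a 2-fold minimum. Of 19 named genes that were called, 11 kept the call without any 1 of the 6 arrays, among them Psat1, Dtl, Ccnd1, Mx1, Papss2, Gad1 and Pdx1. Between 4 h and 8 h, 37 genes were higher and 16 lower at both times, against 0.541 and 0.214 for independent calls; such simulations gave 0 to 122 shared genes (mean 1.49).

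At 24 h 27 of 56 genes of mitosis and G2/M rose. Mki67, a marker of cycling cells, rose 8.63-fold (9.15 ± 0.39 against 6.04 ± 0.29, 3.11 ± 0.74 on the log2 scale, adjusted p = 0.0367). Stmn1, a microtubule destabilizer, rose 7.09-fold (2.83 ± 0.36), Top2a, the topoisomerase that untangles chromosomes, 5.82-fold, and Cks2, a partner of cyclin-dependent kinases, by 2.35 ± 0.45 from 4.93 ± 0.12. The largest rises of this comparison were in genes of secreted Reg proteins, which acinar cells make: Reg3a by 5.97 ± 0.94 (62.5-fold), Reg2 by 5.38 ± 1.15, Reg3b by 5.18 ± 0.67, Reg3g by 5.02 ± 0.72 and Reg1 by 4.03 ± 0.95. Clps, the lipase cofactor made by acinar cells, rose 14.7-fold. Meg3, a noncoding RNA, fell by 1.14 ± 0.28 and Mdm2 by 0.54 ± 0.11. Pdx1 (-0.29 ± 0.20, adjusted p = 0.62) did not pass. Further probe sets read 0.15 for Mki67 (adjusted p = 0.738), 0.01 for Stmn1 (adjusted p = 0.984), -0.24 for Reg2 (adjusted p = 0.656), 1.21 for Reg1 (adjusted p = 0.0589) and -1.04 for Meg3 (adjusted p = 0.336), and did not pass.

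Of 56 mitosis and G2/M genes, 27 rose, 0 fell and 29 were not called at 24 h; adjusted over the list alone 47 rose (median 1.15, adjusted p = 9.59e-48; adjusted p = 0.115 with an estimated correlation). Of 24 acinar markers, 6 rose and 18 did so adjusted over the list alone (median 2.54, adjusted p = 4.02e-22; adjusted p = 0.321 with an estimated correlation). Of 58 oxidative phosphorylation genes, 7 rose, among them Atp5o (2.02-fold) and Ndufa6 (2.27-fold), and 18 adjusted over the list alone (median 0.33, adjusted p = 1.13e-14; adjusted p = 0.321 with an estimated correlation). Of 32 proteasome genes, 4 rose, among them Psmd13 and Psma5, and 12 adjusted over the list alone (median 0.28, adjusted p = 6.76e-08; adjusted p = 0.321 with an estimated correlation). Of 69 ribosome biogenesis genes, 3 rose and 5 adjusted over the list alone, with a median of 0.02 (adjusted p = 0.00743; adjusted p = 0.721 with an estimated correlation). That call ended without untreated replicate 2 (adjusted p = 0.108) or replicate 2 at 24 h (adjusted p = 0.0698). Beta cell function genes had a median of -0.23 with 0 of 37 called and 3 lower adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.67 with an estimated correlation, 0.87 with acinar and leukocyte covariates).

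At 24 h 130 genes were called, 113 higher and 17 lower. The count was 78 and 85 without untreated replicate 2 or 3, 36 and 54 without replicate 2 or 3 at 24 h, 50 in the 6 arrays alone, 244 with array weights, 63 with a 2-fold minimum, 16 with acinar and leukocyte covariates, and 85 with the Gapdh 3′ excess as a covariate. Of 20 named genes that were called, Reg3a, Reg3b, Reg3g, Stmn1, Atp5o and Muc1 kept the call without any 1 of the 6 arrays. With the marker covariates 3 of the 20 kept it, and with the Gapdh covariate 12. The Gapdh covariate ended the calls of Mki67, Top2a, Reg1, Meg3, Mdm2, Psma5 and Psmd13, among others.

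**Figure D2:**
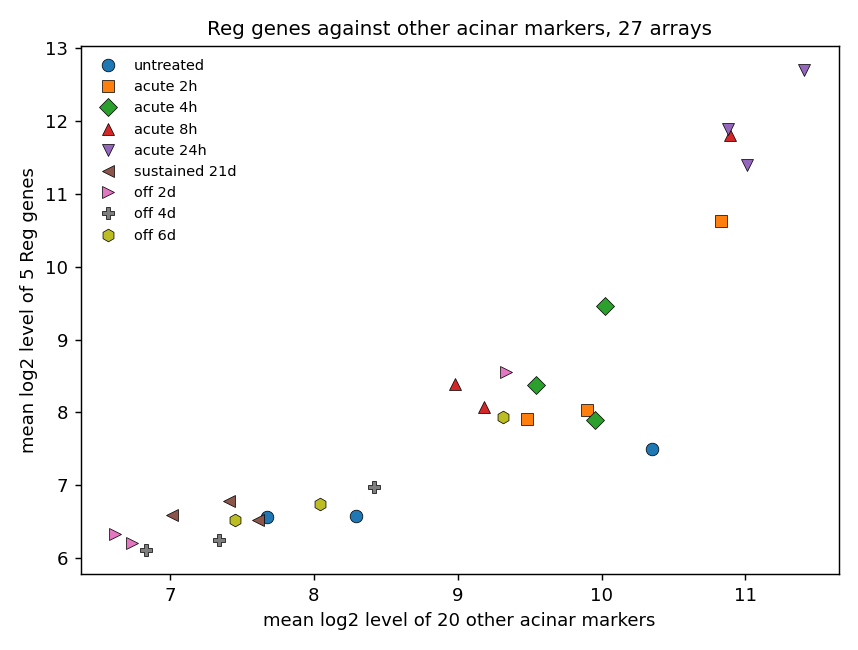
Mean log2 level of 5 Reg genes (vertical axis) against that of 20 other acinar markers (horizontal axis) in each of the 27 arrays, with a symbol per group. The 24 h arrays lay at 11.4 to 12.7 for the Reg genes and 10.9 to 11.4 for the other markers, while untreated replicate 1 lay at 7.49 and 10.3. Replicate 3 at 8 h lay at 11.8 and 10.9, and replicate 3 at 2 h at 10.6 and 10.8.

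After 21 days of daily drug, 6 of 37 beta cell function genes and 7 of 37 genes of the unfolded protein response were called lower than in untreated islets. Abcc8, the sulfonylurea receptor of the potassium channel that gates insulin release, fell by 1.88 ± 0.30, Slc2a2 by 1.63 ± 0.42, Pdx1 by 1.01 ± 0.20 and Ero1b, an oxidase that folds proinsulin, by 1.74 ± 0.19. Xbp1, a transcription factor of the unfolded protein response, fell by 1.86 ± 0.24 (7.91 ± 0.17 against 9.77 ± 0.04), and Creld2 and Manf, secreted proteins of that response, by 2.27 ± 0.20 and 1.42 ± 0.30. The other Abcc8 probe set read -0.023, adjusted p = 0.909. Mx1 fell by 3.76 ± 0.41, Papss2 fell by 3.21 ± 0.32 and Th by 2.23 ± 0.29. Iapp, the beta cell peptide hormone amylin, was -0.16 ± 0.17 (adjusted p = 0.598) and the Ins2 probe set 100150_f_at, near the top of the scale, was -0.09 ± 0.11 (adjusted p = 0.635), so neither passed the test. The other Ins2 probe set, 161849_r_at, fell by 0.65 (adjusted p = 0.000421), and by 0.47 against 24 h (adjusted p = 0.00397).

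Other genes rose at 21 days. Dlk1, a membrane protein of endocrine and fetal tissues, rose 13.0-fold (11.31 ± 0.24 against 7.61 ± 0.18, adjusted p = 7.62e-08), Cox6b2, a subunit of cytochrome c oxidase, 8.53-fold, and Cidea, a protein of lipid droplets, 6.06-fold. Foxo3, a transcription factor restrained by insulin signalling, rose 3.03-fold, Txnip, an inhibitor of thioredoxin, 2.59-fold, Ccng2, a cyclin of quiescent cells, 3.40-fold and Gadd45b, a growth arrest gene, 3.51-fold. Stmn1 rose 3.10-fold, though its other probe set read 0.053 (adjusted p = 0.792), and Rad21, a cohesin subunit, 3.12-fold, while Mki67 did not pass (1.02 ± 0.74, adjusted p = 0.393). Utp4 and Npm1 of ribosome assembly rose 2.19-fold and 2.42-fold, and Nme2 and Odc1, enzymes of nucleotide and polyamine synthesis, fell by 1.27 ± 0.23 and 0.85 ± 0.21. The endothelial genes Tie1 and Emcn fell by 1.27 ± 0.28 and 1.18 ± 0.30, and Vegfa, a growth factor for blood vessels, by 1.13 ± 0.27. Of 26 endothelial markers, 1 rose and 3 fell, 1 and 4 adjusted over the list alone, and the list was not called (median -0.06, adjusted p = 0.197; adjusted p = 0.795 with an estimated correlation), though it passed without untreated replicate 3 (adjusted p = 0.0483). An Esr1 probe set (93945_at), at 12.06 ± 0.15 in untreated islets, fell by 1.59 ± 0.28, and a different one (93946_at), at 7.57 ± 0.12, read 0.35, adjusted p = 0.0433. The sources used here do not say whether any Esr1 probe set reads the estrogen receptor part of MycER. Other probe sets did not pass for Cox6b2 (-0.40, adjusted p = 0.208), Gadd45b (0.53, adjusted p = 0.0682), Txnip (0.37, adjusted p = 0.116), Tie1 (-0.57, adjusted p = 0.0957) and Emcn (-0.13, adjusted p = 0.397), while 1 more for Cox6b2 (1.21) and 1 more for Emcn (-1.11) passed.

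Of 56 mitosis and G2/M genes, 13 rose, 0 fell and 43 were not called at 21 days; 21 rose adjusted over the list alone (median 0.56, adjusted p = 9.31e-07; adjusted p = 0.721 with an estimated correlation). Of 37 genes of the unfolded protein response, 7 fell and 1 rose; adjusted over the list alone 11 fell and 2 rose (median -0.24, adjusted p = 0.00302; adjusted p = 0.542 with an estimated correlation). Of 37 beta cell function genes, 6 fell and 31 were not called, also 6 adjusted over the list alone (median -0.14, adjusted p = 0.0309; adjusted p = 0.795 with an estimated correlation), a call that ended without untreated replicate 2 (adjusted p = 0.0895) or 3 (adjusted p = 0.0873), or without dim probe sets (adjusted p = 0.129). Ribosome biogenesis genes did not pass as a list (4 higher and 6 lower of 69, 5 and 7 adjusted over the list alone, adjusted p = 0.801), nor did the classical Myc induced genes (3 higher and 3 lower of 36, 4 and 4 adjusted over the list alone, adjusted p = 0.762). Acinar markers were lower in 21 of 24, with 0 called and 7 lower at an unadjusted p under 0.05 (median -1.47, adjusted p = 0.00202; adjusted p = 0.801 with an estimated correlation), which ended without untreated replicate 1 (adjusted p = 0.172).

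At 21 days 1354 genes were called against untreated islets, 656 higher and 698 lower. The count was 882 without replicate 2 at 21 days and 268 with a 2-fold minimum, and 25 of 29 named genes that were called kept the call without any 1 of the 6 arrays. Of the genes called at 8 h, 30 were higher and 45 lower at both times and 4 opposite, against 7.55 and 5.33 for independent calls; for 24 h and 21 days these were 29, 6 and 4 genes, against 8.98 and 1.44. Simulations that moved the 21 day changes to other genes gave 1 to 89 shared genes with 8 h (mean 10.8) and 0 to 71 with 24 h (mean 8.05).

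**Figure D3:**
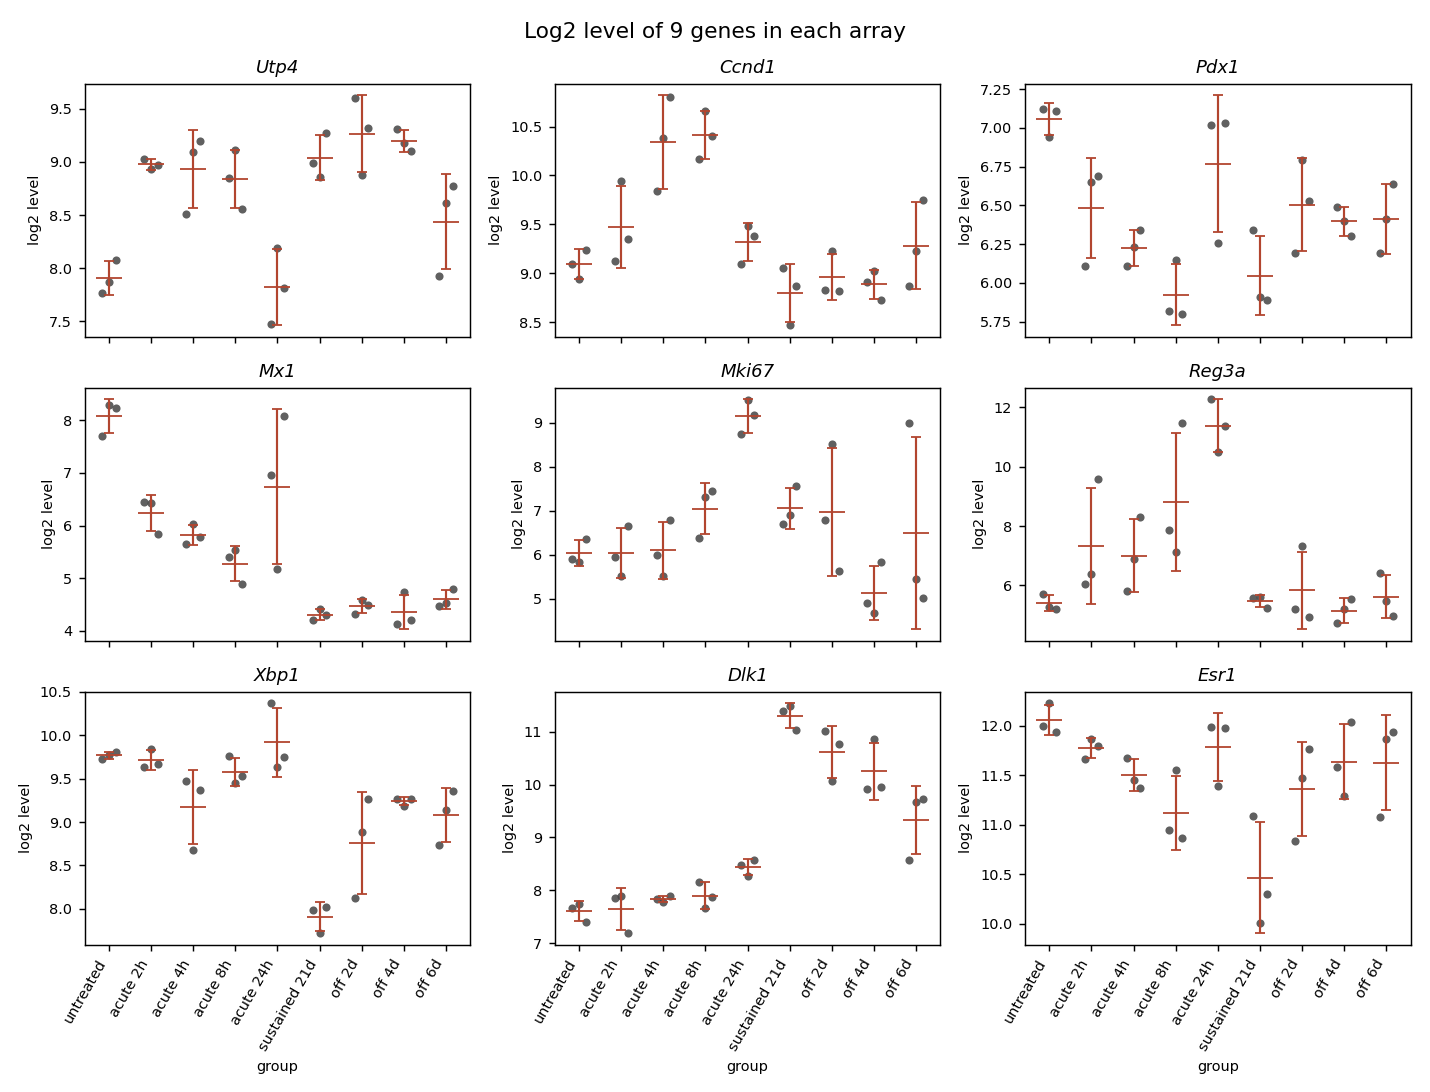
Log2 level of 9 genes in each of the 27 arrays (points), with the group mean (horizontal mark) and SD (bars, n = 3). Mx1 read 8.07 in untreated islets and 4.31 at 21 days on average, and Dlk1 7.61 and 11.31.

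The direct comparison of 21 days with 24 h asked how sustained and acute activation differ. Some genes of mitosis, translation and the endoplasmic reticulum were lower at 21 days. Aurka, a mitotic kinase, fell by 1.73 ± 0.34, Top2a by 1.82 ± 0.56 and Mki67 by 2.09 ± 0.74 (adjusted p = 0.0494). Creld2 fell by 2.99 ± 0.20 (adjusted p = 1.4e-08), Xbp1 by 2.01 ± 0.24, Manf by 1.97 ± 0.30 and Vars, the valine tRNA synthetase, by 1.26 ± 0.18. Odc1, Nme2 and Atp5c1 fell by 1.06 ± 0.21, 1.49 ± 0.23 and 1.12 ± 0.28. Dlk1 rose 7.29-fold (2.87 ± 0.29), Cidea 5.92-fold, Txnip 2.69-fold, Foxo3 2.32-fold and Jun, an immediate early transcription factor, 1.89-fold. The largest falls were of acinar genes, the pancreatic ribonuclease Rnase1 by 7.06 ± 1.34 and Pnliprp1, a lipase-related protein, by 6.01 ± 1.09, with Reg3a falling by 5.90 ± 0.94. A second Mki67 probe set read 0.11, adjusted p = 0.62, and the Mki67 call ended in each of the 6 fits that left out 1 array. With acinar and leukocyte covariates Mki67 read 0.10 and Rnase1 0.48, neither passing; with the Gapdh covariate Mki67 and Top2a did not pass.

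Of 56 mitosis and G2/M genes, 18 fell and 2 rose at 21 days against 24 h; adjusted over the list alone 20 fell and 4 rose (median -0.56, adjusted p = 2.06e-06; adjusted p = 0.73 with an estimated correlation, 0.893 with acinar and leukocyte covariates). Of 49 translation factors and tRNA synthetases, 20 fell and 3 rose, 23 and 6 adjusted over the list alone (median -0.40, adjusted p = 1.14e-05; adjusted p = 0.373 with an estimated correlation). Of 37 genes of the unfolded protein response, 17 fell and 2 rose, 17 and 3 adjusted over the list alone (median -0.29, adjusted p = 1.34e-05; adjusted p = 0.321 with an estimated correlation). Of 58 oxidative phosphorylation genes, 17 fell and 0 rose, 17 and 2 adjusted over the list alone (median -0.09, adjusted p = 0.00466; adjusted p = 0.795 with an estimated correlation), which ended without replicate 3 at 24 h (adjusted p = 0.0538). Of 24 acinar markers, 21 fell, also 21 adjusted over the list alone (median -4.42, adjusted p = 3.21e-17; adjusted p = 0.321 with an estimated correlation).

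Between 21 days and 24 h 1796 genes were called, 939 higher and 857 lower. The count was 1106 without replicate 3 at 24 h, 1101 without replicate 2 at 21 days, 2900 with array weights, 329 with a 2-fold minimum, and 310 with acinar and leukocyte covariates. With the Gapdh covariate it was 1388. Of 21 named genes, 19 kept the call without any 1 of the 6 arrays, 9 with the marker covariates and 19 with the Gapdh covariate. The 21 day arrays belong to the 12 arrays of long treatment and withdrawal and the 24 h arrays to the 15 others, so that these calls are confounded with the division between the sets.

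**Figure D4:**
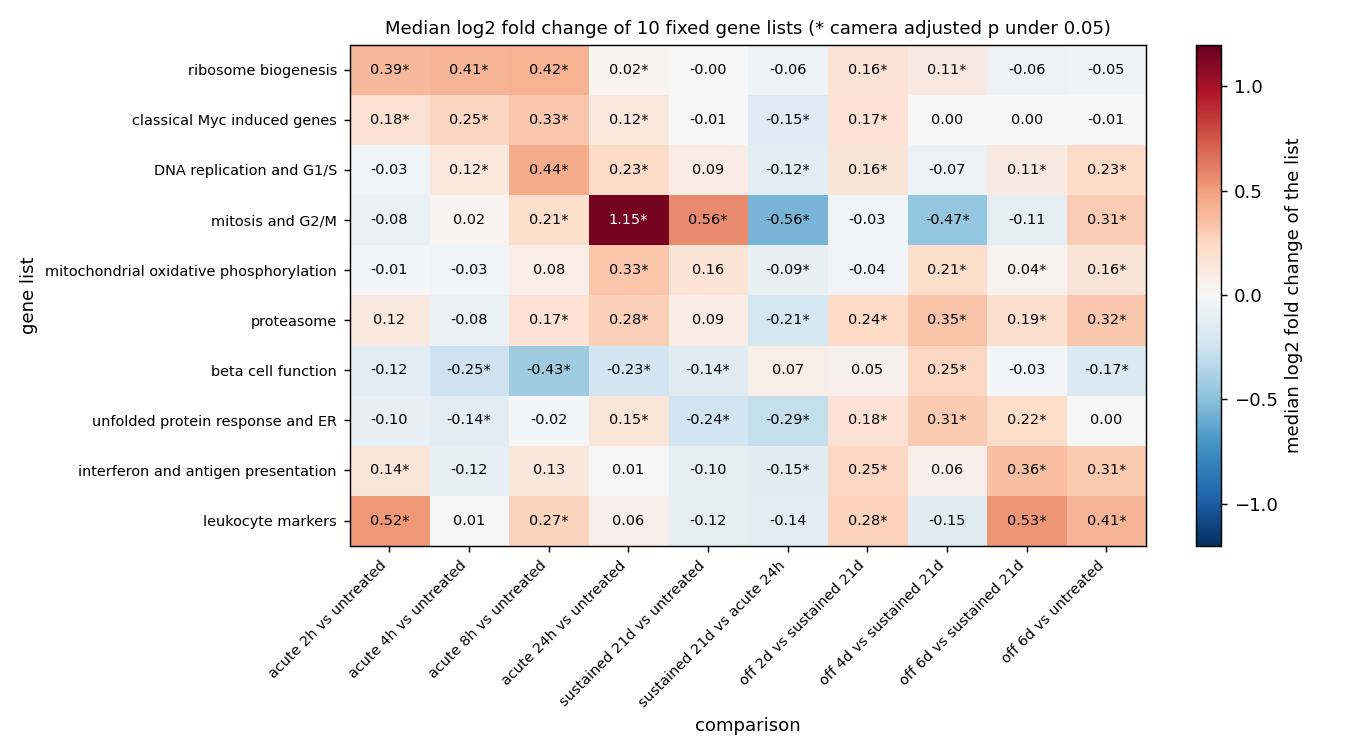
Median log2 fold change of 10 fixed gene lists (vertical axis) in the 10 comparisons (horizontal axis), with a star where the camera adjusted p was under 0.05 at the preset correlation. Mitosis and G2/M read 1.15 at 24 h and 0.56 at 21 days, and ribosome biogenesis 0.39, 0.41 and 0.42 at 2, 4 and 8 h.

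The arrays taken after withdrawal asked which changes of the 21 day course went back. At 2 days off drug limma called few genes against 21 days, with 1366 of 8251 at an unadjusted p under 0.05. Smc3, a cohesin subunit, rose 2.46-fold (1.30 ± 0.24, adjusted p = 0.0334), the tRNA synthetases Hars and Tars 2.36-fold and 1.91-fold, the mitochondrial ribosomal protein Mrps22 2.14-fold, Sdha, a subunit of succinate dehydrogenase, 1.96-fold and the proteasome subunit Psma4 1.89-fold. Kdm5b, a histone demethylase, fell by 0.53 ± 0.09. Of 69 ribosome biogenesis genes 0 were called and 9 rose adjusted over the list alone (median 0.16, adjusted p = 8.98e-06; adjusted p = 0.436 with an estimated correlation). Of 32 proteasome genes 1 rose and 7 adjusted over the list alone (median 0.24, adjusted p = 1.19e-05; adjusted p = 0.464 with an estimated correlation). Leukocyte markers were higher in 38 of 52, with 0 called and 1 higher at an unadjusted p under 0.05 (median 0.28, adjusted p = 0.0215; adjusted p = 0.886 with an estimated correlation). This call ended without replicate 3 at 21 days (adjusted p = 0.144) or without replicate 1 or 2 at 2 days off (adjusted p = 0.0695 and 0.822), and turned with the Gapdh covariate (adjusted p = 0.859).

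At 2 days off 14 genes were called, 13 higher and 1 lower. The count was 0 without replicate 1 or 2 at 21 days, or replicate 2 or 3 at 2 days off (limma; 896, 886, 981 and 887 genes at an unadjusted p under 0.05), 47 without replicate 3 at 21 days and 67 without replicate 1 at 2 days off. It was 31 after quantile normalization, 446 with array weights and 5 with a 2-fold minimum. It was also 0 in the 6 arrays alone, with the marker covariates, without 4 leukocyte-rich arrays and with the Gapdh covariate (1219, 1320, 993 and 1034 genes at an unadjusted p under 0.05), and none of 9 named genes kept the call in all 6 fits that left out 1 array.

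At 4 days off drug 14 of 37 genes of the unfolded protein response and 4 of 37 beta cell function genes were called higher than at 21 days. Abcc8 rose 3.23-fold (11.56 ± 0.21 against 9.87 ± 0.33), Ero1b 1.82-fold and Sytl4, a protein of insulin granules, 1.81-fold. Manf rose 2.73-fold, the chaperone Hspa5 2.61-fold and Pdia6, a disulfide isomerase, 2.54-fold. Msmo1, Idi1 and Sqle, enzymes of cholesterol synthesis, rose 2.63-fold, 2.10-fold and 1.79-fold, and Psma4 2.07-fold. Sox4, a transcription factor, fell by 1.66 ± 0.29, the mitotic kinesins Kifc1 and Kif20a by 1.25 ± 0.22 and 0.99 ± 0.24, Cidea by 1.08 ± 0.24, Cox6b2 by 1.07 ± 0.23, Dlk1 by 1.06 ± 0.29 and Txnip by 0.81 ± 0.20. The Esr1 probe set 93945_at rose 2.25-fold (adjusted p = 0.0247), while the probe set 93946_at read -0.41, adjusted p = 0.0428. Mki67 did not pass (-1.92 ± 0.74, adjusted p = 0.107). Nor did other probe sets of Abcc8 (0.047, adjusted p = 0.784), Pdia6 (0.17 and 0.90, adjusted p = 0.476 and 0.0805), Cox6b2 (-0.37 and -0.54, adjusted p = 0.238 and 0.0954), Kif20a (-0.81, adjusted p = 0.0789) and Txnip (-0.45, adjusted p = 0.0787).

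Of 37 genes of the unfolded protein response, 14 rose and 1 fell at 4 days off; adjusted over the list alone 17 rose and 2 fell (median 0.31, adjusted p = 2.06e-06; adjusted p = 0.321 with an estimated correlation). Of 32 proteasome genes, 10 rose and 14 adjusted over the list alone (median 0.35, adjusted p = 1.4e-07; adjusted p = 0.321 with an estimated correlation). Of 37 beta cell function genes, 4 rose and 0 fell, 6 and 2 adjusted over the list alone (median 0.25, adjusted p = 0.0036; adjusted p = 0.721 with an estimated correlation). Of 56 mitosis and G2/M genes, 4 fell and 5 adjusted over the list alone (median -0.47, adjusted p = 2.06e-06; adjusted p = 0.73 with an estimated correlation). Of 58 oxidative phosphorylation genes, 8 rose and 12 adjusted over the list alone (median 0.21, adjusted p = 0.000372; adjusted p = 0.721 with an estimated correlation).

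At 4 days off 570 genes were called, 373 higher and 197 lower, that is 65.4% higher; per-array median centring gave 513 genes with 79.1% higher. Without replicate 1 at 4 days off limma called 0 genes (1524 at an unadjusted p under 0.05), so none of 27 named genes kept the call there; the count was 204 and 182 without replicate 2 or 3 at 4 days off, and 120 and 34 without replicate 1 or 2 at 21 days, with 2361 under array weights, 70 with a 2-fold minimum and 295 with the Gapdh covariate. That covariate left 19 of the 27 calls and ended those of Idi1, Cidea, Dlk1, Kif20a and the Esr1 probe set 93945_at, among others.

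At 6 days off drug Dlk1 fell by 1.98 ± 0.29 (9.33 ± 0.65 against 11.31 ± 0.24), Cox6b2 by 1.89 ± 0.23, Cidea by 1.76 ± 0.24, Ddit4, an inhibitor of mTOR signalling, by 1.39 ± 0.27 and Foxo3 by 0.88 ± 0.17 from their levels at 21 days. Bzw2 fell by 1.01 ± 0.16 and Jun by 0.83 ± 0.13. Xbp1 rose 2.25-fold, Creld2 2.07-fold, Psma4 1.88-fold and H2-K1, a class I antigen-presenting protein, 1.83-fold. Other probe sets of Cox6b2 (-0.11 and -0.53, adjusted p = 0.853 and 0.245) and H2-K1 (1.0 and 0.13, adjusted p = 0.0691 and 0.637) did not pass. Of 37 genes of the unfolded protein response, 2 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.22, adjusted p = 1.74e-05; adjusted p = 0.321 with an estimated correlation). Of 32 interferon and antigen presentation genes, 1 rose and 8 adjusted over the list alone (median 0.36, adjusted p = 3.83e-10; adjusted p = 0.321 with an estimated correlation). In the same arrays leukocyte markers were higher in 46 of 52 (median 0.53, adjusted p = 4.58e-08; adjusted p = 0.618 with an estimated correlation), with 0 called and 14 higher at an unadjusted p under 0.05. Acinar markers were higher in 23 of 24, with 0 called and 0 at an unadjusted p under 0.05 (median 1.02, adjusted p = 0.00164; adjusted p = 0.796 with an estimated correlation), a call that ended without replicate 1 at 6 days off (adjusted p = 0.33) and without the leukocyte-rich arrays (adjusted p = 0.182).

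At 6 days off 28 genes were called against 21 days, 10 higher and 18 lower. The count was 13, 8 and 14 without replicate 1, 2 or 3 at 21 days, 10 with the marker covariates and also 10 with the Gapdh covariate, 13 without the 4 leukocyte-rich arrays, 56 after quantile normalization (23.2% higher against 35.7%) 12 with a 2-fold minimum, 894 with array weights and 0 in the 6 arrays alone (1027 at an unadjusted p under 0.05). Dlk1, Cox6b2, Cidea, Bzw2, Stmn4 and Jun, of 14 named genes, kept the call without any 1 of the 6 arrays. The Gapdh covariate left 7 of the 14 and ended the calls of Xbp1, Creld2, H2-K1, Psma4, Ddit4 and Foxo3, among others.

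Of the 1354 genes called at 21 days against untreated islets, 115 were called in the opposite direction at 1 or more of the times after withdrawal (8.49%). They numbered 3 at 2 days off, 109 at 4 days off (39 that had risen and 70 that had fallen) and 20 at 6 days off (13 and 7). With 1 array left out they ran from 0 to 18 at 2 days off, from 0 to 151 at 4 days off, with 0 when replicate 1 at 4 days off was missing, and from 6 to 33 at 6 days off. Simulated tables that shared the 21 day arrays gave at most 1 with no change after withdrawal, and 13 to 96 (mean 30.2) when the changes after withdrawal were moved to other genes. The count was 43 and 16 without replicate 1 or 2 at 21 days, 16, 50 and 55 without replicate 1, 2 or 3 at 4 days off, 26 with a 2-fold minimum, 482 with array weights and 61 with the Gapdh covariate. The median share of the 21 day change that had gone back was 6.09% at 2 days, 14.1% at 4 days and 25.6% at 6 days off; the simulations with no change gave up to 19.0%, 21.1% and 22.5%, since the groups share the 21 day arrays.

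Against untreated islets, many changes were still present at 6 days off drug. Mx1 fell by 3.47 ± 0.41, Papss2 fell by 2.75 ± 0.32, Creld2 by 1.23 ± 0.20, Ero1b by 0.98 ± 0.19 and Pdx1 by 0.64 ± 0.20 (adjusted p = 0.0368). The endothelial genes Emcn and Tie1 fell by 1.43 ± 0.30 and 1.27 ± 0.28, and Vegfa by 1.45 ± 0.27, while the Ins2 probe set 161849_r_at fell by 0.41 (adjusted p = 0.0137) and 100150_f_at did not pass (-0.08, adjusted p = 0.698). Nor did other probe sets of Emcn (-0.11, adjusted p = 0.49) and Tie1 (-0.33, adjusted p = 0.382), while 1 more for Emcn passed (-1.22, adjusted p = 0.024). Of 26 endothelial markers, 2 fell, also 2 adjusted over the list alone, and the list was not called (median -0.083, adjusted p = 0.183; adjusted p = 0.795 with an estimated correlation), though it passed without untreated replicate 3 (adjusted p = 0.0458). Dlk1 was 3.29-fold higher, Gadd45b 3.51-fold, Rad21 3.19-fold, Npm1 2.51-fold, Ndufab1, a carrier protein of respiratory complex I, 2.63-fold and Psma5 2.29-fold. Of 32 proteasome genes, 9 rose and 1 fell, 12 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.000136; adjusted p = 0.511 with an estimated correlation). Of 37 beta cell function genes, 6 fell, also 6 adjusted over the list alone (median -0.17, adjusted p = 0.0235; adjusted p = 0.795 with an estimated correlation). Of 56 mitosis and G2/M genes, 6 rose, also 6 adjusted over the list alone (median 0.31, adjusted p = 1.22e-05; adjusted p = 0.783 with an estimated correlation). Leukocyte markers were higher in 42 of 52, with 0 called higher and 1 lower (median 0.41, adjusted p = 0.0109; adjusted p = 0.883 with an estimated correlation). Without replicate 1 at 6 days off, whose leukocyte marker mean lay 1.04 above that of all arrays, the last 3 lists did not pass (adjusted p = 0.791, 0.348 and 0.791), and with the Gapdh covariate the leukocyte list (adjusted p = 0.21) and Pdx1 did not. The beta cell list also missed without untreated replicate 2 (adjusted p = 0.0765) or 3 (adjusted p = 0.104), or without dim probe sets (adjusted p = 0.167).

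At 6 days off 1115 genes were called against untreated islets, 459 higher and 656 lower. The count was 595 without untreated replicate 1, 30 in the 6 arrays alone, 1755 with array weights and 208 with a 2-fold minimum, and 15 of 22 named genes kept the call without any 1 of the 6 arrays. Of the 1354 genes called at 21 days, 670 (49.5%) were called in the same direction at 6 days off, 248 higher and 422 lower, and 0 in the opposite direction. Both comparisons used the same untreated arrays, and simulations that moved the changes of 6 days off to other genes gave 38 to 245 genes called in the same direction (mean 72.0). That count was 362 without untreated replicate 1, 93 with a 2-fold minimum and 25 in the 6 arrays alone.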

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

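The tests of acinar material, the tests of the genes that went back after withdrawal and of those called at both 8 h and 21 days, and the fits with marker or Gapdh covariates or without leukocyte-rich arrays were chosen only after the results they bear on were seen.

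The change from untreated islets differed between 24 h and 21 days, tested directly as 21 days against 24 h with limma, for 1796 genes and 12 gene lists. The lists were lower at 21 days. Their camera adjusted p were 3.21e-17 for acinar markers, 2.06e-06 for mitosis and G2/M, 1.14e-05 for translation factors and tRNA synthetases, and 1.34e-05 for the unfolded protein response. They were 0.00306 for interferon and antigen presentation, 0.00466 for oxidative phosphorylation, 0.00867 for protein folding chaperones, 0.0222 for nucleotide and polyamine synthesis and 0.0225 for the proteasome. They were 0.0301 for classical Myc induced genes, 0.0429 for glycolysis and lactate export and 0.0467 for DNA replication and G1/S. With an estimated correlation none of the 12 passed (adjusted p from 0.321 to 0.886), and with acinar and leukocyte covariates the mitosis list did not (0.893), while DNA replication and G1/S passed in the other direction, higher at 21 days (0.0168). The Gapdh 3′ excess, a sign of RNA quality, was 4.83 ± 0.08 at 21 days and 3.78 ± 0.11 at 24 h; with it as a covariate 1388 genes were called, and the lists of interferon and antigen presentation (0.0533), the proteasome (0.06), glycolysis (0.148) and DNA replication (0.102) did not pass. The actin 3′ excess went the other way, 2.39 ± 0.35 at 21 days and 2.70 ± 0.24 at 24 h, and was not tried as a covariate. This comparison sets some of the 12 later arrays against some of the 15 others, so separate processing, which stays open below, is confounded with it. The last 5 of these lists and the chaperones and oxidative phosphorylation lost the call without at least 1 array, among them replicate 3 at 24 h for chaperones (0.0636) and oxidative phosphorylation (0.0538), and replicate 2 at 24 h for DNA replication (0.383), classical Myc induced genes (0.0698) and nucleotide synthesis (0.0694). The proteasome list lost it without replicate 2 or 3 at 24 h (0.0508 and 0.0968), and glycolysis without replicate 2 or 3 at 24 h or replicate 1 or 2 at 21 days (0.0577, 0.157, 0.0621 and 0.0629). Classical Myc induced genes and DNA replication also lost it without replicate 1 at 21 days (0.0622 and 0.0996).

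The acinar markers were the largest of these differences, with Clps at 13.15 ± 0.63 and Pnliprp1 at 12.81 ± 0.41 in the 24 h arrays, although laser capture is meant to leave acinar tissue out. The 20 acinar markers outside the Reg family rose by 2.33 ± 0.76 (SE) at 24 h, and their deviations from the group means were correlated across the 27 arrays (mean pairwise r 0.691; markers are not independent of each other), consistent with acinar cells taken along in varying amounts. The 5 Reg genes, 4 of which stand on the acinar list, rose by 5.12 ± 0.88, and by 2.93 ± 0.67 with the other acinar markers as a linear covariate, which argues against acinar material like that of untreated samples as the whole cause of their rise. A change inside acinar cells next to the islets, a relation to acinar RNA that is not linear, and a change in islet cells under active MycER stay open, the last as untested. With acinar and leukocyte covariates 16 genes were called at 24 h, with 130 without them.

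Fewer genes were called at 2 and 6 days off drug (14 and 28) than at 4 days off (570), and replicate 2 at 2 days off and replicate 1 at 6 days off had leukocyte marker means 0.534 and 1.04 above that of all arrays. If lymphoid material in these arrays widened the spread, leaving the 4 leukocyte-rich arrays out would raise the counts, but they were 0 at 2 days off and 13 at 6 days off (limma; 993 genes at an unadjusted p under 0.05 at 2 days off). That does not decide, because fits with 2 arrays in a group lost or gained calls whichever array was left out. Without its replicate 1, which is not among these arrays, 4 days off also gave 0 (limma, 1524 at an unadjusted p under 0.05). By contrast, 2 days off without its replicate 1 gave 67, and 6 days off without its replicate 3 gave 31. Array weights, which count uneven arrays less, gave 446, 2361 and 894 genes at 2, 4 and 6 days off. Against the mean of all arrays, replicate 2 at 2 days off also read 0.48 for acinar markers (-2.22 and -2.15 in its group) and 0.77 for blood and nerve markers. Replicate 1 at 6 days off read 0.35 for acinar markers (-1.49 and -0.96 in its group) and 1.08 for blood and nerve markers. Material of any of these kinds and a real difference between the days off cannot be told apart. The groups of 2 and 6 days off have 3 arrays each, and 1 of them is highest in all these markers.

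The 12 arrays of long treatment and withdrawal stood apart from the 15 untreated and acute ones, with 1354 genes called at 21 days and 1115 at 6 days off against untreated islets, and 1796 for 21 days against 24 h. Separate processing of the later arrays might add to this; the labels give no dates, and of 33 spike control probe sets 10 differed between the 12 and the 15 arrays at an unadjusted p under 0.05 and 2, CreX-3 and DapX-5, after Bonferroni adjustment, by 0.33 and 0.17 on the log2 scale. No group has arrays in both sets, and although 75 of the genes called at 21 days were called in the same direction at 8 h, within the 15 arrays, that does not decide for them, because simulations with the later shift moved to other genes gave 1 to 89 (mean 10.8) and leaving out 1 array left as few as 27. The 115 genes called in the opposite direction after withdrawal were more than in any simulation with the changes after withdrawal moved to other genes (13 to 96, mean 30.2). They do not decide either, because leaving out 1 array left as few as 16. The simulations used all 27 arrays, so they give no range for that lower count. Separate processing and sustained activation of MycER, which the design names and which was not tested, cannot be told apart here.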

How the results depend on the processing

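Leaving out the leukocyte-rich arrays and the fits with acinar and leukocyte, Eif2s3y or Gapdh covariates were chosen after seeing the data, as was the comparison of 24 h with 8 h; the other alternatives were planned. Where no reason is given, the cause was not tested. A 2-fold minimum, fewer arrays and fewer probe sets change counts by construction.

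Median centring, leaving out dim probe sets, a trend and robust variance, the mean of probe sets, every probe set and the Eif2s3y covariate left the 10 counts within 1.5 times. The labels do not say whether replicate numbers pair the arrays, and the values show no clear pairing but do not exclude it. Correlations of deviations between arrays of the same number ran from -0.442 to 0.544 (mean 0.0201), and between different numbers from -0.642 to 0.661 (mean -0.00939). No comparison lay above 0.1 in all 3 pairs. Against untreated islets all 3 were positive at 8 h (0.0311 to 0.216) and at 6 days off (0.0946 to 0.338). A block for the replicate number, which assumes such pairing, gave 41, 70, 153, 128, 1385, 1812, 17, 559, 34 and 1139 genes in the order of the report, 120 genes that went back, 692 still changed at 6 days off and 109 lists.

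A 2-fold minimum gave 17, 23, 40 and 63 genes at 2, 4, 8 and 24 h, 268 at 21 days, 329 for 21 days against 24 h, 5, 70 and 12 at 2, 4 and 6 days off, and 208 for 6 days off against untreated. It left 26 genes that went back and 93 still changed. The 6 arrays alone gave 0, 14, 4 and 50 genes at 2, 4, 8 and 24 h, 0 at 2 and at 6 days off against 21 days and 30 for 6 days off against untreated, with 25 still changed; at an unadjusted p under 0.05 the zeros were 860, 1219 and 1027 genes. Array weights, whose fit stopped short of its tolerance, gave 103 genes at 2 h, 244 at 24 h, 2900 for 21 days against 24 h, 446, 2361 and 894 at 2, 4 and 6 days off, 1755 for 6 days off against untreated and 482 that went back. Quantile normalization gave 31 genes at 2 days off and 56 at 6 days off. Without the leukocyte-rich arrays the counts were 20 at 2 h, 0 at 2 days off (993 at an unadjusted p under 0.05) and 13 at 6 days off. With acinar and leukocyte covariates they were 90 at 2 h, 16 at 24 h, 310 for 21 days against 24 h, 0 at 2 days off (1320 at an unadjusted p under 0.05), 10 at 6 days off, and 69 for 24 h against 8 h. With the 3′ excess of Gapdh as a covariate they were 85 at 24 h, 0, 295 and 10 at 2, 4 and 6 days off (1034 at an unadjusted p under 0.05 for the 0), 41 for 24 h against 8 h, and 61 genes that went back. At 21 days and at 24 h the Gapdh values of the arrays do not overlap, so that this fit leans on the slope within groups. The same holds for the acinar marker means at 24 h against untreated islets and against 21 days.

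Leaving out 1 array gave 14 to 78 genes at 2 h, 16 to 69 at 4 h, 51 to 208 at 8 h, 36 to 165 at 24 h and 882 to 1219 at 21 days. It gave 1101 to 1593 for 21 days against 24 h, 0 to 67, 0 to 771 and 8 to 31 at 2, 4 and 6 days off, 595 to 1082 for 6 days off against untreated, and 39 to 188 for 24 h against 8 h. Genes that went back ran from 16 to 154, those still changed from 362 to 689, and lists called from 103 to 115. The 2 arrays left in a group are assumed to vary like the other groups.

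Of 109 lists called, 2 held with an estimated correlation; fry called 26 of the 310 tests. Among 194 called results, from a selection of the genes open to naming, 188 kept the call with the block, 191 with median centring, 190 with quantile normalization, 145 with a 2-fold minimum, 95 in the 6 arrays alone 137 with acinar and leukocyte covariates and 155 with the Gapdh covariate. Of 59 such results with another probe set, 17 passed with it, 31 did not and 11 turned. Of 1164 fits of these genes without 1 array, 813 kept the call.

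Directions turned for these genes. Another probe set read -0.45 for Noct and -0.14 for Bop1 at 2 h, -0.037 for Ccnd1 at 8 h, -0.24 for Reg2 at 24 h, -0.40 for Cox6b2 and 0.35 for Esr1 at 21 days, 0.11 for Mki67 at 21 days against 24 h, and -0.18 for Mrpl2 at 2 days off. For Esr1 other probe sets read -0.05, -0.33 and -0.27 at 2 days off, -0.027, -0.41 and -0.28 at 4 days off, and -0.29 and -0.11 at 6 days off. With acinar and leukocyte covariates Rnase1 read 0.48 and Mki67 0.10 at 21 days against 24 h.

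Directions of lists turned with acinar and leukocyte covariates at 2 h (leukocyte markers, adjusted p = 0.914; beta cell function, 0.545), 8 h (leukocyte markers, 0.745; acinar markers, 0.695), and 24 h (acinar markers, 0.692; DNA replication, 0.742). By construction a covariate made from a list takes up that list. They also turned for DNA replication at 21 days against 24 h (0.0168, now higher at 21 days), and for leukocyte markers at 2 days off (0.795), 6 days off (0.754) and 6 days off against untreated (0.941). With the Gapdh covariate leukocyte markers turned at 2 days off (0.859), and without the leukocyte-rich arrays at 8 h (0.935). Ribosome biogenesis at 21 days, not called, turned without dim probe sets (0.805), without untreated replicate 3 (0.837) and without replicate 2 at 21 days (0.875); without 1 array its adjusted p ran from 0.272 to 0.996. Of 78 list calls, 54 held with the covariates, 66 without the leukocyte-rich arrays, 69 without dim probe sets, 76 with Eif2s3y, 70 with Gapdh and 77 with the block. Arrays have no depth. The top of the scale limits the Ins2 probe set 100150_f_at, and low signal limits Myc, Slc16a1, Cks2, Gad1, Rnase1 and Mx1. Low signal may also limit Prim1, Reg3a, Reg3g, Dtl, Mki67, Top2a, Cdc7, Pdx1, Papss2, Mrps22 and Sdha, among others.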

Other observations

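The comparison of 24 h with 8 h and its genes were chosen only after the values were seen; the counts of splits of the arrays were planned.

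Between 8 h and 24 h after the injection, some early genes came down while some mitotic genes went up. Ribosome biogenesis genes were lower at 24 h (median -0.29, 6 of 69 called, 14 adjusted over the list alone, camera adjusted p = 4.86e-13; adjusted p = 0.0947 with an estimated correlation), and so were DNA replication and G1/S genes (median -0.14, 3 of 57 called, 5 adjusted over the list alone, adjusted p = 0.000453; adjusted p = 0.669 with an estimated correlation). Utp4 fell by 1.02 ± 0.22 (SE, n = 3), Cdca7 by 1.59 ± 0.26, Cdc7 by 1.56 ± 0.34, Ccnd1 by 1.09 ± 0.24 and Pdk1 by 1.15 ± 0.25; the other Ccnd1 probe set read -0.093, adjusted p = 0.722. Mitosis and G2/M genes were higher (median 0.73, 18 of 56 called, 38 adjusted over the list alone, adjusted p = 2.32e-23; adjusted p = 0.282 with an estimated correlation). Beta cell function genes were higher as a list (median 0.15, 2 of 37 called, also 2 adjusted over the list alone, adjusted p = 0.00378; adjusted p = 0.669 with an estimated correlation), with Pdx1 0.85 higher (adjusted p = 0.0297) and Papss2 1.38 higher (adjusted p = 0.0299). Mx1 did not pass (1.46, adjusted p = 0.0758).

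In this comparison limma called 177 genes, 109 higher and 68 lower at 24 h. The count was 39 without replicate 1 at 8 h, 79 without replicate 2 and 41 without replicate 3 at 24 h, 69 with acinar and leukocyte covariates, and 41 with the Gapdh covariate (Gapdh 3′ excess 3.78 ± 0.11 at 24 h and 4.78 ± 0.24 at 8 h). The actin 3′ excess was 2.70 ± 0.24 at 24 h and 2.53 ± 0.29 at 8 h. Acinar markers were higher at 24 h (median 1.68, 1 of 24 called, 2 adjusted over the list alone, adjusted p = 3.6e-07; adjusted p = 0.669 with an estimated correlation), as were duct markers (median 0.32, 4 of 14 called, 5 adjusted over the list alone, adjusted p = 8.12e-05; adjusted p = 0.0947 with an estimated correlation).

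After withdrawal Mki67 differed widely between arrays of a group. It read 8.52 in replicate 2 at 2 days off, with 6.79 and 5.63 in the others, and 8.99 in replicate 1 at 6 days off, with 5.45 and 5.03 in the others. These are the arrays of their groups with the highest means of leukocyte markers, of acinar markers, and of blood and nerve markers.

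The 6 arrays of a comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In each of the 10 comparisons 1 of the 10 splits, the real one, called as many genes as the real one. Each other split mixes the real groups and moves their difference into the spread. Low counts there thus follow wherever the groups differ, whatever the cause. The real count and the highest of the other splits were 40 and 0 at 2 h, 75 and 1 at 4 h, 158 and 1 at 8 h, 130 and 1 at 24 h, 1354 and 0 at 21 days, and 1796 and 0 for 21 days against 24 h. They were 14 and 1 at 2 days off, 570 and 0 at 4 days off, 28 and 3 at 6 days off, and 1115 and 4 for 6 days off against untreated.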
